A study of Mus musculus with 6 samples.

How the data were processed

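Liver RNA from 3 wildtype and 3 insulin-deficient diabetic male mice was measured on an Affymetrix array focused on genes of glycan synthesis, glycan binding and related signalling, with 1 sample per array. Per the submitters' processing notes the values were made with RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set; its version and settings are not given in the sources used here. The deposited values were treated as log2 expression values, since they ran from 2.03 to 13.45, and the array medians lay between 4.93 and 5.06. No detection call was used, so a low value was not separated from background, and the number of arrays limits the precision. Because normalization between arrays had already been applied by the authors, a change shared by most probe sets would not be visible in these values.

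All 1246 probe sets were tested. Of these, 984 carried a RefSeq accession and 963 of them were named through a RefSeq gene table of the assembly GRCm38.p6, used for names only and with no coordinates taken from it. That gave 909 genes. The other 283 probe sets stayed unnamed, among them 261 with a UCSC transcript identifier. There were 48 genes with several probe sets. Each such gene was represented by its probe set with the highest mean over all arrays, and disagreement between probe sets of a named gene is stated. Probe sets whose suffix marks possible cross-hybridisation were kept.

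Diabetic was compared with wildtype by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The fit had 4 residual and 2.44 prior degrees of freedom. Differences are diabetic minus wildtype on the log2 scale, with the moderated standard error (SE) and its 95% confidence interval. Group values are means ± SD. The design text speaks of mice, but the labels do not spell out that every array came from a separate animal; if some did not, the p-values would measure only the spread between these samples.

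Before the data were examined, 28 gene lists were fixed, and the first 4 of them were joined into 1 list of glycosaminoglycan (GAG) synthesis enzymes, which made 29. The 26 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The mean over each list's members was also compared by an exact two-sided permutation test, which with 3 arrays against 3 cannot go below 0.1. The genes named in the text were chosen by a rule fixed before the data were examined. It took up to 10 probe sets per direction with the largest differences among those past the threshold and with no overlap between the groups, filled up to 5 per direction by smallest unadjusted p, up to 4 members of each list by p, and 31 set genes, of which 28 were measured and 3 were not analysed here.

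Both groups carry replicate numbers 1 to 3. Deviations from the group means, over all probe sets, correlated at 0.397 for the arrays numbered 1, 0.138 for those numbered 2 and 0.162 for those numbered 3. All 3 exceeded the limit set for treating the numbers as pairs, so a fit with the replicate number as a block is given beside each result whose call it changed. The labels do not say what a shared number stands for.

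The alternatives were a shift of each array to a common median, quantile normalization, leaving out the dimmer probe sets, eBayes with a trend and robust setting, array weights, the replicate block, and leaving out each array in turn. For counts there were also an ordinary linear model without moderation and an adjusted p threshold of 0.10. For lists there were camera with an estimated correlation, fry, and all probe sets of a gene. A planned run with control probe sets and those of other organisms could not be made, because the table showed no such rows.

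The scripts were tested on simulated data that took each probe set's mean and residual SD from the real arrays, with 200 of the 1246 probe sets changed, in 20 simulations of the comparison of diabetic with wildtype. The calls recovered 63.3% of probe sets changed by 0.5 on the log2 scale, 90.6% of those changed by 1 and 98.0% of those changed by 2, and 4.40% of calls were false. A first form of this test, replaced after it had been run, drew the spreads from limma's prior, which follows the fit's own assumptions; it gave 58.7%, 90.9% and 98.4% for the same sizes, with 4.37% of calls false. With so many changed probe sets the adjusted threshold is easier to pass than with few, so these shares are not the power for a small number of changes. The simulated arrays were also independent of each other. They lacked the deviations that real arrays of the same number shared, so the shares of recovered and false calls do not cover that structure. In simulations of the GAG enzymes among 909 genes, camera called a fall of 0.1 in 20 of 20 runs and no fall in 0 of 20. Those values were drawn independently between genes. With list members correlated at 0.107, the value estimated from the real list, camera called a fall of 0.1 in 15 of 20 runs and a fall of 0.2 in 20 of 20, and it called the unshifted list in 4 of 20, in either direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.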

Results

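The data are 6 expression arrays of mouse liver, 3 from wildtype males and 3 from males with insulin-deficient diabetes, each giving log2 values for 1246 probe sets of a focused glycan gene array. The study asked whether enzymes that make glycosaminoglycans, the sulfated sugar chains of proteoglycans, are less expressed in diabetic liver, in connection with the clearance of plasma lipids. The arrays' number sets the precision: the median SE of a difference was 0.11 on the log2 scale.

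Papss2, which makes the universal sulfate donor PAPS, was 1.82-fold higher in diabetic liver, at 10.52 ± 0.08 against 9.66 ± 0.14 (log2, SD, n = 3 per group). Mbl2, a mannose-binding lectin that the liver secretes into plasma, was 2.04-fold higher, at 12.25 ± 0.09 against 11.23 ± 0.22. Btg2, an antiproliferative gene, was 1.62-fold higher, at 5.78 ± 0.10 against 5.08 ± 0.06. The unnamed probe set of the transcript uc009mbb.1 was 1.93-fold higher, at 8.72 ± 0.14 against 7.77 ± 0.15. All diabetic arrays lay above all wildtype arrays for these 4 probe sets.

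**Figure D1:**
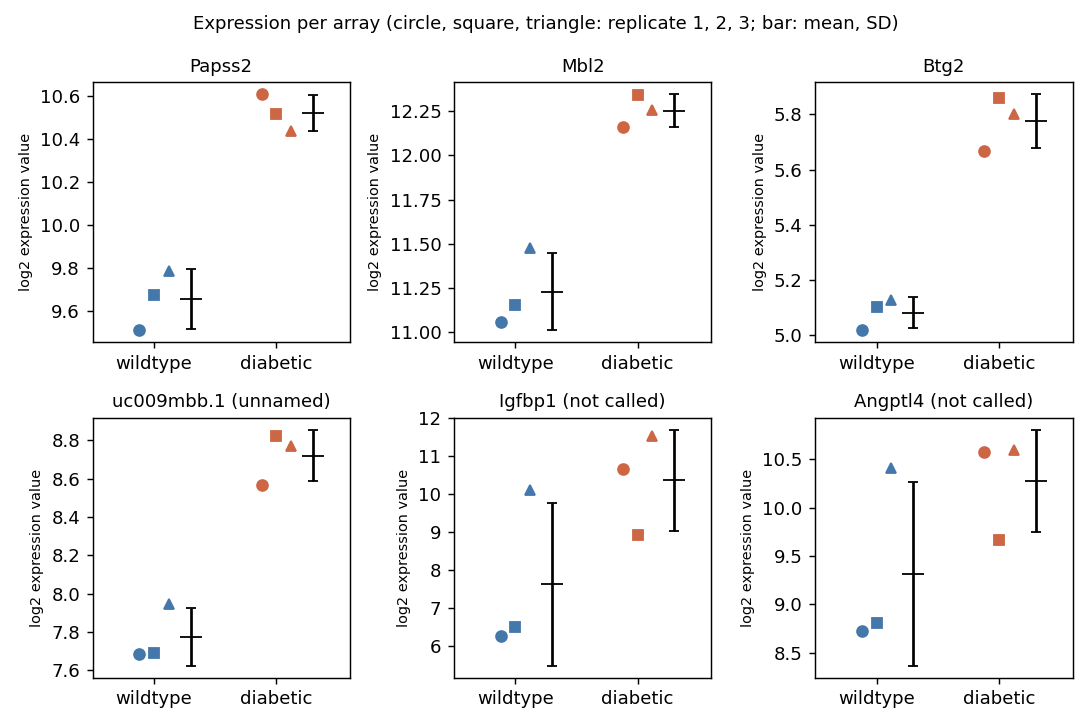
Log2 expression values per array for the 4 probe sets called by limma and for Igfbp1 and Angptl4, which were not called; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD. The groups do not overlap for the 4 called probe sets, whereas wildtype 3 lies among the diabetic arrays for Igfbp1 and Angptl4.

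The log2 differences were 0.87 (SE 0.10, 95% confidence interval 0.63 to 1.11) for Papss2, 1.03 (SE 0.13, 0.72 to 1.33) for Mbl2, 0.70 (SE 0.08, 0.49 to 0.90) for Btg2 and 0.95 (SE 0.11, 0.67 to 1.22) for uc009mbb.1, each with a limma adjusted p of 0.0412. These 4 were the probe sets past the threshold among 1246, with 4 higher and 0 lower. At an unadjusted p under 0.05 limma gave 37 probe sets, 23 higher and 14 lower. The groups did not overlap for 98 probe sets, or 7.87%, where chance gives 10% if all groupings of the arrays are equally likely. Levels shared by same-numbered arrays would change that share. With the replicate number as a block, limma called 0 probe sets, with adjusted p = 0.215 for Papss2 and 0.142 for Mbl2, Btg2 and uc009mbb.1. The blocked fit gave 54 at an unadjusted p under 0.05. Both counts, 37 and 54 of 1246, lay under the share of 0.05 that chance alone gives on average. The calls were also lost with the trend and robust setting and without moderation (0 each), and leaving out any 1 array left 0, or 1 (Mbl2) without wildtype 3.

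Among values that did not pass, the smallest p in the higher direction after these belonged to Ugp2, which makes UDP-glucose, at 9.53 ± 0.21 in diabetic and 8.76 ± 0.26 in wildtype liver, a difference of 0.77 (limma adjusted p = 0.619). In the lower direction Shh, a secreted developmental signal, differed by -0.73 (adjusted p = 0.485), with -0.18 at its other probe set. Hes6, a transcription factor of the Hes family, differed by -0.87 and -0.84 at its 2 probe sets (adjusted p = 0.707 and 0.725). With the replicate block, limma's adjusted p was 0.142 at both Hes6 probe sets, the same as for Mbl2, Btg2 and uc009mbb.1. That fit gave 0.195 for Ugp2 and 0.494 for Shh at the probe set with the larger difference. In the blocked fit the 4 probe sets called without it thus did not stand apart from these. The chemokine receptor Cxcr2 differed by -0.34 at a dim probe set and by -0.29 at its brighter one, which gave -0.028 without wildtype 2. Igfals, which stabilises circulating IGF complexes, differed by -0.61, at 9.68 ± 0.18 against 10.29 ± 0.32 (adjusted p = 0.928).

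The comparison of GAG synthesis enzymes came nearest to the study's question. The list was broad and also held hyaluronan synthases and the extracellular sulfatases Sulf1 and Sulf2. Of the 52 measured enzymes, 30 had a lower and 22 a higher mean in diabetic liver, and 0 passed the limma threshold, either over all probe sets or adjusted over the list alone; 2 had an unadjusted p under 0.05. The mean difference over the list was -0.024 on the log2 scale, with list means of 5.25 ± 0.03 in diabetic and 5.27 ± 0.08 in wildtype liver (SD, n = 3 per group; exact permutation p = 0.9). The largest difference in the higher direction was 0.50 for Ust, which sulfates chondroitin and dermatan sulfate, and in the lower direction -0.35 for B4galt1, a galactosyltransferase that also acts on N-glycans; for B4galt1 it ran from -0.57 without diabetic 3 to -0.23 without wildtype 1. For Ust the dimmer probe set gave -0.02.

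Camera gave the list an adjusted p of 0.73, with 0.925 as the adjusted p with an estimated correlation and 0.988 from fry. Without wildtype 2 the list mean changed sign, to 0.023. All 52 confidence intervals excluded a fall of 1 on the log2 scale, but 40 of 52 excluded a fall of 0.5, so smaller falls of single enzymes stayed within the error. Only 22 of the enzymes had means above the array median, and the intervals of 14 of these 22 excluded a fall of 0.5. For the dimmer ones a value near background can hide a difference, so a narrow interval there does not exclude a fall.

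**Figure D2:**
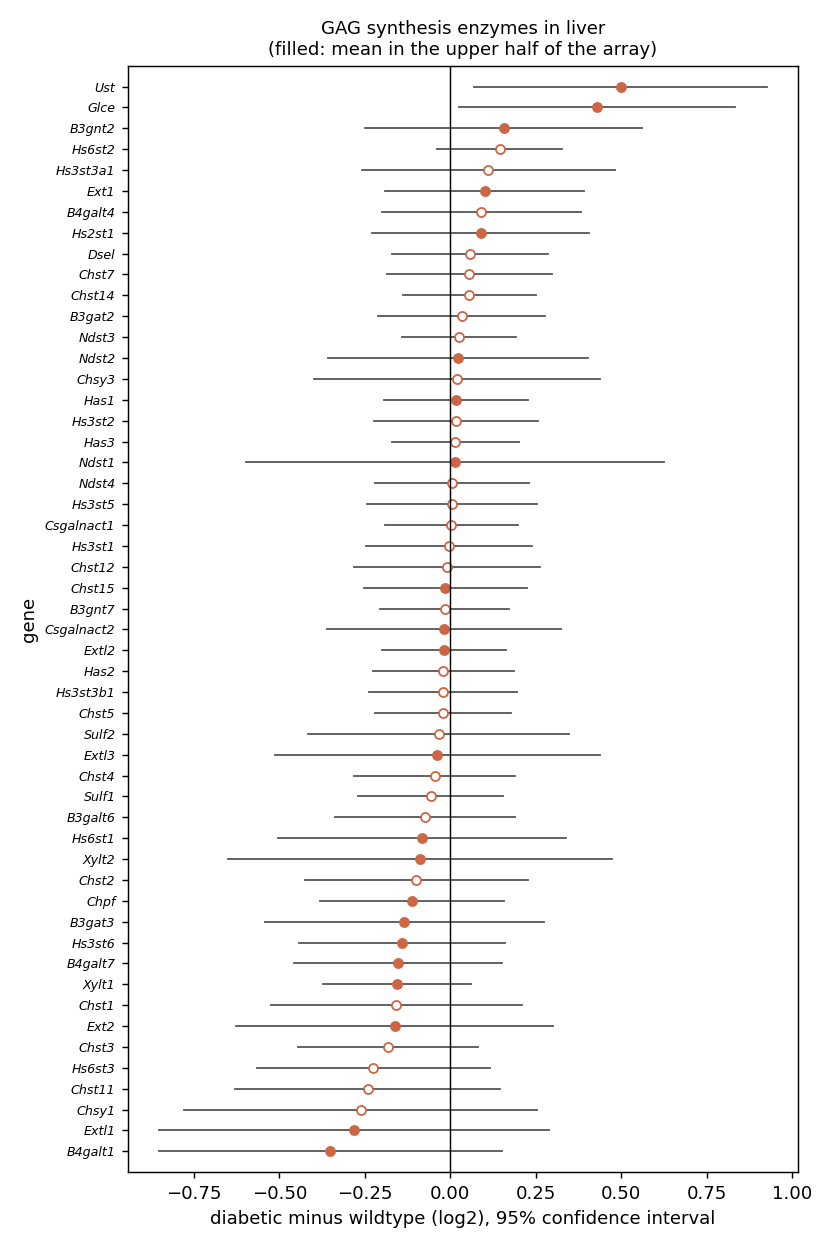
Differences between diabetic and wildtype liver (log2, points) with 95% confidence intervals (lines) for the 52 measured GAG synthesis enzymes; filled points mark the 22 with means above the array median. The intervals of 50 genes include 0.

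Of 11 measured enzymes that start and extend heparan sulfate chains, 9 had lower and 2 higher means, with a list mean of -0.09 (camera adjusted p = 0.73; 0 called). Xylt1 and Xylt2, which attach the first xylose, differed by -0.16 and -0.09, and the chain polymerases Ext1 and Ext2 by 0.10 and -0.16. Without wildtype 3, Xylt2 and Ext2 differed by -0.32 and -0.33, and without wildtype 2 by 0.17 and 0.053. Ext1 ran from 0.0049 without wildtype 1 to 0.22 without wildtype 2, and Xylt1 from -0.21 without diabetic 2 to -0.083 without diabetic 3. Wildtype 2 stood apart, with 40 probe sets over 0.5 above or below every other array, and without it the list mean was 0.019. The list mean was -0.16 without wildtype 3 and -0.12 without wildtype 1. Leaving out 1 diabetic array gave list means between -0.10 and -0.076.

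Among 17 enzymes of heparan sulfate sulfation and epimerisation, 10 had higher and 7 lower means, with a list mean of 0.02 (camera adjusted p = 0.968; 0 called). Glce, the epimerase that makes iduronic acid, was 7.48 ± 0.26 in diabetic and 7.05 ± 0.21 in wildtype liver (SD, n = 3), a difference of 0.43 that did not pass (limma adjusted p = 0.928). The N-deacetylase/sulfotransferases Ndst1 and Ndst2 differed by 0.01 and 0.02. The O-sulfotransferases Hs2st1 and Hs6st1 differed by 0.09 and -0.08. The extracellular sulfatases Sulf1 and Sulf2, with means below the array median, differed by -0.06 and -0.03. Chondroitin and dermatan sulfate enzymes had a list mean of -0.01 over 13 genes (camera adjusted p = 0.821), with 0.00 for the initiating enzyme Csgalnact1. Hyaluronan and keratan sulfate enzymes had a list mean of -0.04 over 11 genes (adjusted p = 0.752).

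Of the sulfate donor genes only 3 were measured, too few for the list test. Papss2 was the 1 member past the threshold. It also passed adjusted over the list alone, which so small a p does as a matter of course. With the replicate block it was not called (limma adjusted p = 0.215). Papss1, the other PAPS synthase, differed by -0.13 and the PAPS transporter Slc35b3 by 0.08. Among 12 genes of GAG degradation 0 passed, with a list mean of -0.02 (camera adjusted p = 0.989, where the test's direction was up). The list mean was 0.086 without wildtype 2 and -0.15 without wildtype 3. Glb1 differed by 0.35, Arsb by 0.24 and Idua by -0.48, and heparanase, Hpse, by 0.12. Without wildtype 3 the differences were 0.17 for Glb1, 0.13 for Arsb and -0.87 for Idua, while Idua differed by -0.26 without wildtype 2.

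Proteoglycan core proteins showed no called change in 28 measured genes, of which 17 had lower and 11 higher means (list mean -0.02, camera adjusted p = 0.752). Sdc1, a hepatocyte heparan sulfate proteoglycan that binds lipoprotein remnants, was 8.90 ± 0.11 in diabetic and 8.46 ± 0.40 in wildtype liver (SD, n = 3), a difference of 0.44 (95% confidence interval -0.04 to 0.92; limma adjusted p = 0.928). Wildtype 2, at 8.91, lay among the diabetic arrays. The Sdc1 difference was 0.67 without wildtype 2 (limma adjusted p = 0.192) and 0.31 without wildtype 1. Sdc4 differed by -0.12, Gpc3 by -0.04, Gpc4 by -0.34 (-0.22 without wildtype 1) and Col18a1 by 0.04. Lipid turnover was covered by 3 genes, all with higher means and 0 called. Angptl4, an inhibitor of lipoprotein lipase, was 10.28 ± 0.53 against 9.31 ± 0.95, a difference of 0.97 with a 95% confidence interval of -0.23 to 2.17. The Angptl4 difference ran from 0.67 without wildtype 1 to 1.51 without wildtype 3.

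In the growth hormone, IGF and insulin list, 7 of 17 genes had higher and 10 lower means, and 0 passed. The list mean was 0.16, its median was -0.03, camera's direction was down (adjusted p = 0.989), and the largest single difference was 2.74 for Igfbp1. Without diabetic 3 the list mean was 0.0021, and without wildtype 1 it was 0.044. Igfbp1, an insulin-repressed IGF-binding protein, was 10.36 ± 1.33 in diabetic and 7.61 ± 2.14 in wildtype liver (SD, n = 3; limma adjusted p = 0.928), with wildtype 3 at 10.09 and the other wildtype arrays at 6.26 and 6.50. Igf1 differed by -0.16, and Igfbp5 by 0.76, which was 0.38 without diabetic 3 and 1.16 without diabetic 1.

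Among 10 hepatocyte and plasma lectins, 5 had higher and 5 lower means, and Mbl2 was the 1 called (list mean 0.06, camera adjusted p = 0.73). Mbl2 also passed adjusted over the list alone, which so small a p does as a matter of course. With the replicate block Mbl2 was not called (limma adjusted p = 0.142). Without wildtype 2 the list mean was 0.20, and without wildtype 1 it was -0.021. Its relative Mbl1 differed by 0.27, and the asialoglycoprotein receptor subunit Asgr1 was 12.32 ± 0.04 in diabetic and 12.32 ± 0.14 in wildtype liver. Fry's test for change in either direction gave this list an adjusted p of 0.0511. Galectins had a list mean of 0.14 over 9 genes (camera adjusted p = 0.821), with 0.55 for Lgals9 (0.36 without diabetic 1); the list mean was 0.069 without diabetic 1 and 0.23 without diabetic 2.

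The other glycan lists held 0 called genes. Nucleotide sugar synthesis had 19 higher and 14 lower means (list mean 0.05, camera adjusted p = 0.821), with 0.53 for Ugdh, which makes UDP-glucuronic acid (0.27 without wildtype 2), 0.37 for the fructokinase gene Khk (0.23 without diabetic 1) and -0.05 for Gfpt1, the entry enzyme of the hexosamine pathway. Nucleotide sugar transporters had a list mean of -0.01 (adjusted p = 0.876), with 0.072 without wildtype 2 and -0.12 without wildtype 3. The dolichol pathway list mean was -0.06 (adjusted p = 0.73) and that of N-glycan trimming and branching was -0.06 (adjusted p = 0.821), with 0.21 for the core fucosyltransferase Fut8 and 0.07 for Mgat4a. Mucin-type O-glycan enzymes had a list mean of -0.03 (adjusted p = 0.73). Sialyltransferases had a mean of -0.01 and a median of 0.02 (adjusted p = 0.821), with -0.06 for St6gal1 and -0.27 for St6galnac3. The ganglioside enzyme St3gal5 differed by 0.54, but by 0.015 without wildtype 2 and 1.16 without wildtype 3. Fucosyltransferases had a list mean of 0.03 (adjusted p = 0.735). Glycosphingolipid enzymes had a mean of -0.01 and a median of 0.00 (adjusted p = 0.821), with 0.21 for B3galt4. Lysosomal glycosidases outside GAG breakdown had a list mean of 0.05 (adjusted p = 0.73), with 0.21 for the sialidase Neu1. The list of O-GlcNAc, O-mannose and GPI anchor genes had a mean of 0.06 (adjusted p = 0.73), with -0.16 for Ogt. Notch genes had a list mean of -0.03 (adjusted p = 0.956), with 0.52 for Notch1 (0.34 without wildtype 3) and -0.90 for its target Hes1.

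**Figure D3:**
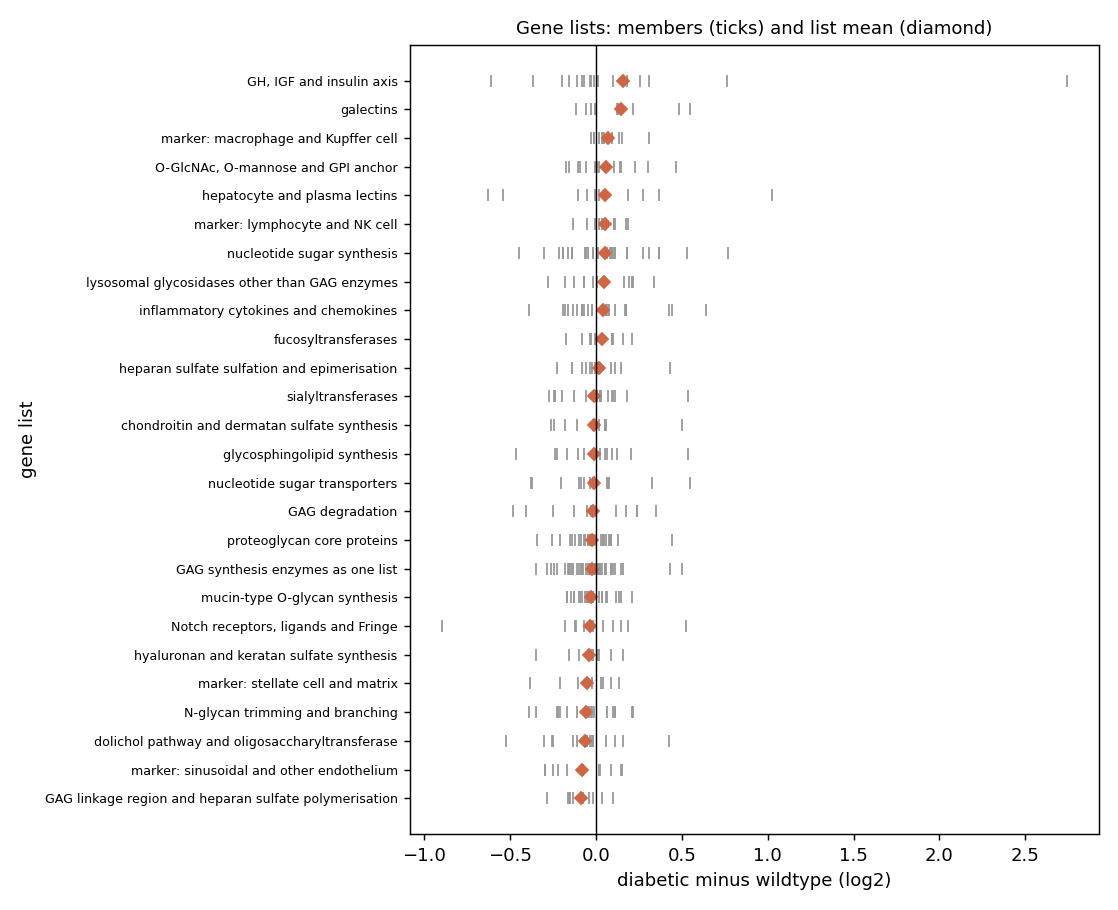
Differences between diabetic and wildtype liver (log2) for the members (ticks) and means (diamonds) of the 26 tested gene lists. The list means lie between -0.09 and 0.16, and 0 lists passed the threshold.

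No marker list of another liver cell type passed the list test. Means above the array median were found for 4 of 11 macrophage, 1 of 11 lymphocyte, 5 of 11 endothelial and 4 of 8 stellate cell markers. The dimmer markers can hide a difference, so these lists do not show that the cell content was unchanged. The camera adjusted p was 0.73 for macrophage (list mean 0.07), lymphocyte (0.05) and endothelial (-0.08) markers and 0.821 for stellate cell markers (-0.05), with -0.38 for Pdgfrb (-0.16 without wildtype 3) and -0.30 for Selp (-0.20 without wildtype 2) as single values. Cholangiocytes were covered by 1 gene and were not tested. Inflammatory cytokines had a list mean of 0.04 (adjusted p = 0.956), with 0.45 for Ccl9 (0.29 without wildtype 3) and 0.64 for Il18 (0.29 without wildtype 2). Of the 26 lists tested, 0 passed by camera, by camera with an estimated correlation, by fry or with the replicate block, and camera gave 0 lists at an unadjusted p under 0.05. The mean of 20 of the 26 lists changed sign when 1 of the 6 arrays was left out, and leaving out 1 array moved between 14 and 22 of the 26 means by over 1.5 times or turned their sign, so the signs and sizes of these list means depended on single arrays.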

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

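The alternatives were planned before the data were examined. The count of 4 called probe sets, all higher in diabetic liver, was 4 after the median shift, with array weights and at the 0.10 threshold, and 3 after quantile normalization and without the dimmer probe sets; those calls were all among the 4. With the replicate block, with eBayes with trend and robust, and with the ordinary linear model, 0 probe sets were called, and 0 were higher. Leaving out 1 array at a time gave between 0 and 1 calls, which have fewer samples behind them. The count of lower probe sets was 0 throughout, and the cause of the lost calls was otherwise not tested. Over the 12 refits, the adjusted p ran from 0.0257 to 0.323 for Papss2, Mbl2 and Btg2 and to 0.392 for uc009mbb.1, while the differences stayed between 0.79 and 0.93 for Papss2, 0.94 and 1.15 for Mbl2, 0.65 and 0.75 for Btg2 and 0.89 and 1.03 for uc009mbb.1. Each replicate number occurs once per group, so the block cannot move a difference, and it changed only the errors and the calls. The GAG list mean ran from -0.056 without wildtype 3 to 0.023 without wildtype 2, a reversed direction whose cause was not tested; it stayed negative and uncalled under the other alternatives, and 0 lists passed under any. With 1 array left out, the mean of 20 of the 26 tested lists changed sign in at least 1 of the 6 refits. The block changed no call other than the 4. Among 71 named genes and probe sets, leaving out 1 array changed the sign of 5 to 11 uncalled differences and quantile normalization of 6. Of the 39 with a difference of at least 0.2 in size, 22 moved by over 1.5 times or turned their sign without at least 1 array. With no detection calls, signal over background limits the dim probe sets.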

Other observations

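The tests of fasting genes and of pancreas and intestine genes were chosen only after the values they address had been seen, and so were the genes named here outside the rule. Arrays of the same replicate number shared several levels across both groups. Msmo1, a cholesterol synthesis enzyme, was 9.61 on wildtype 1 and 10.11 on diabetic 1, against 11.36 to 11.91 on the other arrays. Piga, which starts GPI anchor synthesis, was 8.09 and 7.43 on the arrays numbered 1, against 6.01 to 6.29, and Lgalsl was 7.12 and 6.79, against 4.63 to 5.28. The chemokine Cxcl1 was 8.13 on wildtype 3 and 8.94 on diabetic 3, against 5.23 to 6.02, and the adhesion molecule Vcam1 was 4.91 and 4.60, against 3.24 to 3.54. Diabetic 3 alone had 19 probe sets over 0.5 above every other array; the macrophage gene Adgre1 was 5.18 there, against 3.81 to 4.32, and Csf1r was 7.50, against 6.23 to 6.85.

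The 4 probe sets called higher in diabetic liver were set against other groupings of the 6 arrays. Of the 10 splits into 3 and 3, 1 gave as many calls, the real one, with 4 against at most 0 in the others, also among the 4 splits that part all 3 pairs; 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, 8 of the 10 splits, the real one included, gave at least the real 37 probe sets, and the highest other gave 95, which points to structure among the samples that the groups do not follow. Renormalizing by median or quantiles moved the 4 differences by at most 0.053, less than their smallest SE of 0.084. Level or distribution differences that remained between the arrays thus did not make the 4 differences. The values had already been normalized, and renormalizing cannot undo that step, so whether the authors' normalization was a source is not decided. A response to diabetes stays open.

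Igfbp1 and Angptl4 on wildtype 3, at 10.09 and 10.41, lay at the level of the diabetic arrays, while diabetic 3 was the highest of all for both, and within pairs 1, 2 and 3 diabetic exceeded wildtype by 4.40, 2.40 and 1.43 for Igfbp1 and by 1.85, 0.86 and 0.19 for Angptl4 (limma adjusted p = 0.822 for both with the block). A mislabelled sample was tested on 20 probe sets chosen without that array, where it took a median position of 0.889 between the wildtype mean at 0 and the diabetic mean at 1. The other wildtype arrays, placed likewise, took 0.621 and 0.583 and the diabetic arrays 0.326 to 0.518, so the test did not place arrays of known label either and leaves a wrong label open. For a low insulin or fasting state of that animal, 1 of the 4 genes Fgf21, Igfbp2, Igf1 and Igfals lay beyond both other wildtype arrays in the direction predicted. That gene was Fgf21, at 5.41 against 5.20 and 5.36. Igfbp2, predicted higher, was 11.96 there against 12.93 and 12.99 on those arrays. Between the groups, Fgf21 and Igfbp2 differed by -0.03 and -0.11, so neither was raised in the insulin-deficient mice. Igf1 and Igfals, predicted lower, differed by -0.16 and -0.61. The genes thus cannot decide, and a low insulin or fasting state too stays open. A level shared by the arrays numbered 3, as for Cxcl1 and Vcam1, also stays open and was not tested.

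Reg1, Reg3b and Dmbt1, secreted proteins of gut and pancreas, were high on wildtype 2 alone, at 5.75, 5.76 and 6.80 against at most 3.90, 4.42 and 4.80 elsewhere. If pancreas tissue had been carried into the sample, other pancreas genes may be raised too, but 0 of 4 (Reg2, Reg3d, Muc1 and Chga) exceeded all other arrays by over 0.5, and Reg2 was 4.06 there against at most 4.15. For intestine tissue carried into the sample, 0 of 5 (Reg4, Muc13, Lgals4, Cdhr5 and B3gnt6) did. Muc13, Reg4 and Cdhr5 were higher than the highest other array by 0.32, 0.14 and 0.14. Lgals4, at 8.03, and B3gnt6, at 3.69, were below the highest other array, at 8.79 and 3.70. The criterion for excluding a tissue was changed after its result was known: under the first form the pancreas values would have counted as excluding pancreas, and the form used asks for at least 4 genes with means above the array median, which 1 of the 4 pancreas genes had. The other pancreas genes were dim and may not have shown a rise, so the pancreas values do not decide on that source. Pancreas and intestine both stay open, and no biological explanation was tested.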
